A study of Mus musculus with 8 samples.

How the data were processed

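Gene expression was measured by RNA sequencing in 8 mouse hypothalami taken at postnatal day 19, 4 from pups given vehicle and 4 from pups given PLX3397 by gavage from day 9 to day 15. Each group held 2 females and 2 males, per the labels, and the series design text speaks of 8 hypothalami, so the samples were treated as separate animals; the sample source field reads brain. Per the labels' protocols, total RNA was depleted of ribosomal RNA with biotinylated probes, fragmented and reverse transcribed from random primers. Whether the libraries keep strand is not given in the sources used here.

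The deposited table holds whole-number counts per gene and, beside them, FPKM values (fragments per kilobase, scaled to library size) made by the authors, per the file headers. The submitters' processing notes name bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma and the mouse build mm10, without their roles; the counting tool, its parameters and the annotation release are not given in the sources used here. In the deposited FPKM columns a gene with a count of 0 is listed at 0.0001. Another 126 values with a count above 0 lie at or below 0.0001, so that value does not always stand for no reads. The table lists 55401 genes with coordinates, of which 55141 have an identifier in GENCODE vM21 and 51957 the same coordinates there. Reads of overlapping genes, of antisense partners or of near-identical copies cannot be assigned with certainty from such a table.

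Total counts ran from 54115300 to 60001808 in the vehicle libraries and from 55900335 to 67487391 in the PLX3397 libraries. A count of 0 allows up to 3 counts, or 0.0451 to 0.0557 counts per 1000000 (CPM) depending on the library. This limit covers counting error only. No pair of libraries of a group agreed within sampling noise, so none was treated as a repeat of another. Expression of Xist and Ddx3y matched the sex label in all 8 libraries.

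The design written before the data were examined assumed normalized values and named limma-trend on log2(FPKM + 0.5) as the test. Because the table also held counts, the test became edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM scaling, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test was applied to the 16894 genes with a mean FPKM of at least 0.5, leaving 38507 untested. The installed default of the dispersion step was kept. Its newer bias-adjusted form is an alternative, and the counts from both had been seen when the default was kept. PLX3397 was compared with vehicle over all 8 libraries with sex as a covariate. The effects within females and within males and their difference came from a model with 4 groups, which share an estimate of the spread. Females were compared with males with treatment as a covariate. Log2 fold changes are PLX3397 against vehicle unless said otherwise, and levels are CPM as mean ± SD. Errors of fold changes, called standard errors here, were derived from the test. Each is the absolute log2 fold change divided by the square root of the F statistic.

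Of 41 gene lists fixed before the data were examined, 38 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2(FPKM + 0.5) with a preset correlation between genes of 0.01. The same test with a correlation estimated for each list, and fry, were alternatives. Every camera p is adjusted over the 38 lists. Of 692 list symbols, 691 matched the table. Gene Ontology terms came from the deposited table's own annotation column. Terms with 10 to 500 tested genes were tested with Fisher's exact test, one-sided, against the 13481 tested genes that carry any term.

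Genes named in the text follow a rule fixed in advance. It takes Csf1r, Agrp, Npy, Pomc, Acan and Hapln1 in every case. For the comparison of treatments it takes the 10 called genes with the highest and the 10 with the lowest fold change, with a mean FPKM of at least 1, separate group values and no predicted-gene symbol. For each list described it takes up to 4 members with the smallest p. For the effects within a sex and their difference it takes 3 genes per direction by adjusted p, and for females against males 5. Genes named outside the rule are said to be so, apart from C1qa, Gh, Prl, Cga and Hbb-bs, which describe single libraries and were chosen after their values were seen, and genes named only for an overlap or a plot's range, and 2 genes within it are not reported here.

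Alternatives covered other expression filters, pseudocounts, scalings, covariates, the replicate label as a block, limma-trend variants, DESeq2 1.42.0 and leaving out each library in turn. After the data had been seen, fits without the libraries vehicle F1 and PLX3397 M2, other edgeR settings and a fit on counts summed over overlapping genes were added. The tests were checked on simulated counts with 200 changed genes drawn from the real means and library sizes. In the comparison of treatments, run on 16894 genes, edgeR recovered 26 of 67 genes changed 1.5-fold, 45 of 67 changed 2-fold and 55 of 66 changed 4-fold, with 9 false calls among 135. For the difference between the sexes it recovered 0, 3 and 38 of these, with 6 false calls among 47. In the simulated comparison of treatments DESeq2 recovered 44 of 67, 53 of 67 and 57 of 66, with 62 false calls among 216.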

Results

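Microglia, the resident macrophages of the brain, depend on signalling through the receptor CSF1R, and PLX3397 is an inhibitor of that receptor used to remove them. The series asks what microglia contribute to the postnatal development of the hypothalamus, in particular of the AgRP neurons, which drive feeding, and of perineuronal nets, the matrix that coats some neurons. Hypothalami from 4 vehicle and 4 PLX3397 pups, 2 females and 2 males in each group, were profiled on postnatal day 19, 4 days after the last gavage day. Total counts were 57888914, 58529790, 54115300 and 60001808 in vehicle F1, F2, M1 and M2. They were 67487391, 64785049, 58606826 and 55900335 in PLX3397 F1, F2, M1 and M2. The share of counts on mitochondrially encoded genes was 4.68 ± 0.162% in vehicle and 5.19 ± 0.228% in PLX3397 libraries (SD, n = 4 each).

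Transcripts of microglia were far lower after PLX3397. Csf1r, the receptor the compound blocks (chromosome 18, 61100598 to 61131134, mm10), fell 18.1-fold, from 81.0 ± 3.81 CPM in vehicle to 4.69 ± 2.38 CPM in PLX3397 libraries (SD, n = 4 each; log2 fold change −4.18 ± 0.43, edgeR adjusted p = 0.00526). P2ry12, the purinergic receptor that guides microglial processes (chromosome 3, 59216272 to 59262871), fell 29.0-fold, from 19.9 ± 3.19 to 0.683 ± 0.165 CPM (−4.86 ± 0.22, adjusted p = 0.000793). Tmem119, a membrane protein gene used as a microglial marker, fell from 13.2 ± 1.20 to 2.42 ± 0.463 CPM (−2.44 ± 0.16, adjusted p = 0.00215). Each of these 3 genes was lower in all 4 PLX3397 libraries than in any vehicle library.

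Of the 30 microglial genes tested, 23 fell and 0 rose, and 29 fell when adjusted over the list alone. Their median log2 fold change was −3.47 (camera adjusted p = 5.39e-43; adjusted p = 0.195 with an estimated correlation). Selplg, the P-selectin ligand, was among them (−3.84, edgeR adjusted p = 0.00306). The 10 lowest named genes of the whole comparison were mostly of this kind: Crybb1 (−6.23), Neu4 (−5.13), Fcrls (−5.00), P2ry12, Ltc4s (−4.47), P2ry13 (−4.30), Ctss (−4.21), Csf1r, Itgam (−4.12) and C1qc (−3.96), with adjusted p between 0.000793 and 0.0477. Without a library in turn, Crybb1 passed in 4 of 8 fits, Fcrls and Itgam in 3, P2ry13 in 2 and Ltc4s in 0, and the other 5 in all 8. Neu4, a sialidase, belongs to the oligodendrocyte precursor list instead. The library PLX3397 M2 held the least of these transcripts. Its Csf1r was 1.23 CPM, against 5.04 to 6.44 CPM in the other 3 PLX3397 libraries. Its C1qa count was 0, which allows up to 0.0542 CPM.

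**Figure D1:**
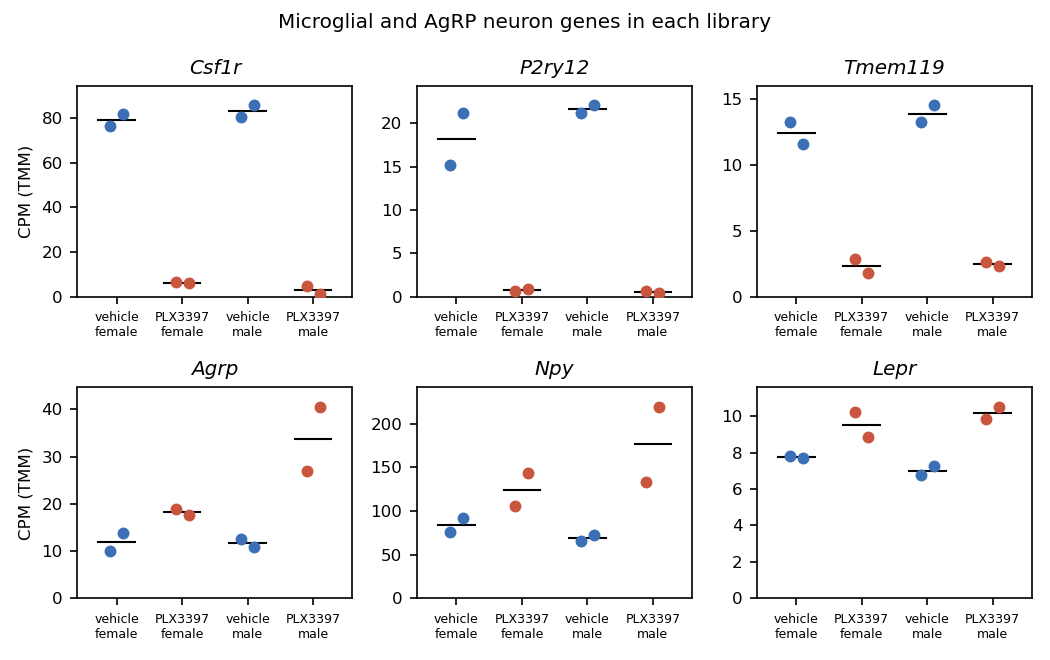
Levels in CPM of 3 microglial genes (Csf1r, P2ry12, Tmem119) and 3 AgRP neuron genes (Agrp, Npy, Lepr) in each of the 8 libraries, by sex and treatment, with points for libraries and horizontal lines for means of 2. Csf1r lies between 76.4 and 85.7 CPM in vehicle and between 1.23 and 6.44 CPM in PLX3397 libraries, whereas Agrp is higher in PLX3397 libraries and highest in PLX3397 M2.

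Transcripts of macrophages at the brain's borders and of immune molecules that myeloid cells carry were lower as well. Of 14 border-macrophage genes 10 were under the expression filter and not tested. All 4 tested border-macrophage genes fell: Mrc1, the mannose receptor (−3.71, edgeR adjusted p = 0.00806), the scavenger receptor Stab1 (−1.94, adjusted p = 0.00518), Cbr2 (−1.54, adjusted p = 0.0407) and the transcription factor Maf (−0.55, adjusted p = 0.00927). Adjusted over the list alone, these 4 also fell, and the list was too short for camera. Of 15 genes of activated or phagocytic microglia, 6 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.000104; adjusted p = 0.216 with an estimated correlation). The falling ones included the tetraspanin Cd9 (−1.26), Cd74 (−1.45), lysozyme Lyz2 (−1.16) and cathepsin Ctsl (−0.31), with edgeR adjusted p from 0.0046 to 0.0421, and the rising one was Spp1, which encodes osteopontin (0.69, adjusted p = 0.0498). Of 10 antigen presentation genes 3 fell (4 adjusted over the list alone): the invariant chain Cd74 (adjusted p = 0.02), B2m (−0.41, adjusted p = 0.0373) and the class II gene H2-Eb1 (−1.14, adjusted p = 0.0469). That list passed camera (adjusted p = 0.000239; adjusted p = 0.396 with an estimated correlation), H2-K1 had −0.64 (edgeR adjusted p = 0.189), and all 10 members had a negative sign. Cd74 and Lyz2 passed in 2 of the 8 fits without a library, Ctsl and H2-Eb1 in 1, and B2m and Cbr2 in 0. Of 14 complement genes 4 fell and 0 rose (5 and 2 adjusted over the list alone): the integrin subunit Itgb2 (−2.80, adjusted p = 0.0046), C1qc, C1qb (−3.47, adjusted p = 0.0204) and Itgam. The list missed the camera threshold (adjusted p = 0.0669, or 0.459 with an estimated correlation) but passed with fry (adjusted p = 0.0147). C1qb and Itgam passed in 3 of the 8 fits.

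Genes of the oligodendrocyte lineage, the cells that make myelin, were lower in PLX3397 hypothalami. Neu4 (chromosome 1, 94020451 to 94028334) fell 35.1-fold, from 32.0 ± 1.89 to 0.972 ± 0.803 CPM (SD, n = 4 each; −5.13 ± 0.49, edgeR adjusted p = 0.0046). Of 18 precursor genes 12 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of −0.93 (camera adjusted p = 1.06e-18; adjusted p = 0.283 with an estimated correlation). Besides Neu4, the kinase Fyn fell by 0.69 on the log2 scale (edgeR adjusted p = 0.00404). The matrix genes Tnr, which encodes tenascin-R (−0.93), and Vcan, versican (−1.27), fell with adjusted p = 0.0046 each. Of 23 mature oligodendrocyte and myelin genes 8 fell and 0 rose (21 and 0 adjusted over the list alone), and all 23 had a negative sign, with a median of −1.06 (camera adjusted p = 1.74e-16; adjusted p = 0.396 with an estimated correlation). Myrf, the transcription factor of myelin genes, fell by 1.67 on the log2 scale (edgeR adjusted p = 0.014), the connexin gene Gjc3 by 1.34 and Enpp2, autotaxin, by 1.06 (adjusted p = 0.0218 and 0.0247). Chosen after their values were seen, Gpr17, Bcas1 and Enpp6, which mark newly committed cells, had −2.55, −2.61 and −2.50 (adjusted p = 0.0046, 0.00958 and 0.00951), whereas Pdgfra, the receptor of early precursors, had −0.21 (adjusted p = 0.182). The mean log2 level of the myelin list was 6.73 to 7.27 in vehicle and 5.82 to 6.39 in PLX3397 F1, F2 and M1, and 5.37 in PLX3397 M2. Myrf, Gjc3 and Enpp2 passed in 5, 3 and 2 of the 8 fits that leave out a library, whereas Neu4, Fyn, Tnr and Vcan passed in all 8.

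**Figure D2:**
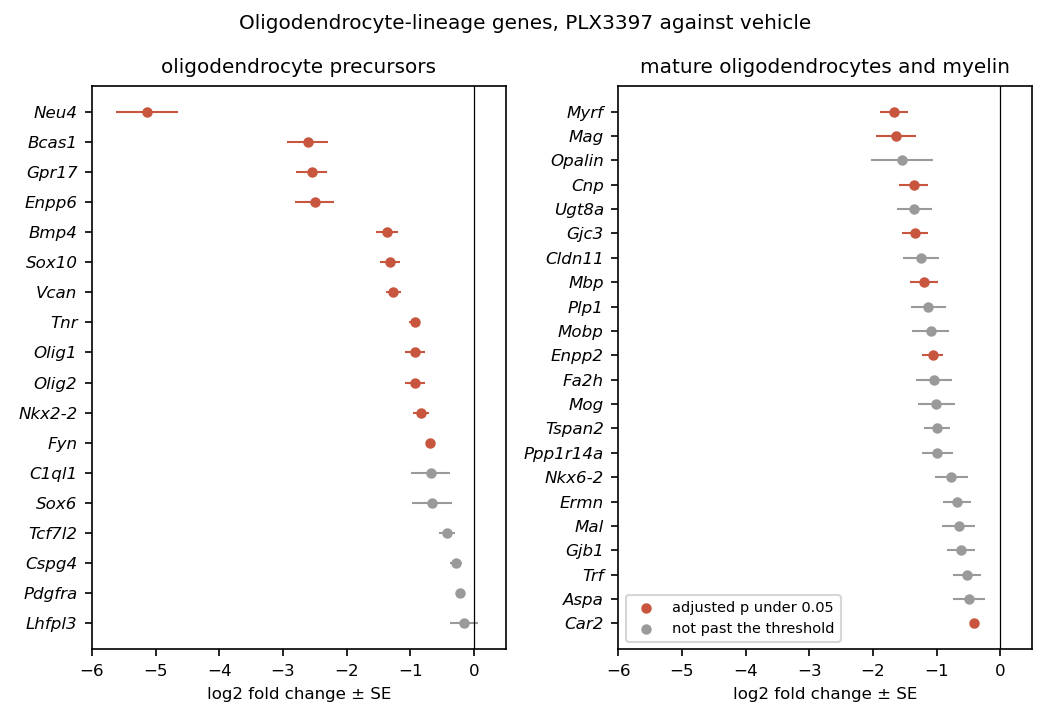
Log2 fold changes with standard errors (edgeR, PLX3397 against vehicle, 4 libraries each) of the 18 tested members of the precursor list and of 22 of the 23 of the mature oligodendrocyte and myelin list. All genes drawn lie below 0, from −5.13 for Neu4 to −0.16 for Lhfpl3.

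Perineuronal nets are built from chondroitin sulfate proteoglycans, hyaluronan link proteins and tenascin-R. Acan, whose product aggrecan is the core proteoglycan of the nets (chromosome 7, 79053483 to 79115099), was 6.02 ± 0.351 CPM in vehicle and 5.90 ± 0.376 CPM in PLX3397 libraries (SD, n = 4 each; −0.03 ± 0.10, edgeR adjusted p = 0.921). That difference lies within the spread between libraries, and its sign turned under quantile normalization (0.040) and without PLX3397 M1 (0.0099) or vehicle M2 (0.020). Hapln1, a link protein gene, was 10.5 ± 1.24 and 8.42 ± 0.365 CPM (−0.31 ± 0.09, adjusted p = 0.168). Of 16 net genes 3 fell and 0 rose (4 and 0 adjusted over the list alone): Tnr, Vcan and the brevican gene Bcan (−0.42, adjusted p = 0.0441), of which Tnr and Vcan are also in the precursor list. The list missed the camera threshold (adjusted p = 0.0813, or 0.398 with an estimated correlation) but passed with fry (adjusted p = 0.0147). Its median was −0.10. Of 20 chondroitin sulfate synthesis genes 2 fell and 0 rose, over all genes and adjusted over the list alone: the sulfotransferases Chst3 (−1.74, adjusted p = 0.00951) and Ust (−0.57, adjusted p = 0.00654). Csgalnact1 and Xylt1 had −0.22 and −0.17 (adjusted p = 0.34 and 0.317), and the list's camera adjusted p was 0.044 (adjusted p = 0.33 with an estimated correlation). The list lost that call without PLX3397 F1 or M1 or vehicle F2 or M2 and under median-ratio scaling and quantile normalization. Of 24 matrix protease and inhibitor genes 3 fell and 0 rose (4 and 0 adjusted over the list alone). The list's camera adjusted p was 0.11, or 0.398 with an estimated correlation, and its fry adjusted p 0.0147. The 3 were Cemip2, named for cell-surface hyaluronan breakdown (−1.02, edgeR adjusted p = 0.000993), Ctss, also in the microglia list, and the proteoglycan-cleaving Adamts4 (−2.04, adjusted p = 0.0261). Plat, tissue plasminogen activator, had −0.41 (adjusted p = 0.112). Bcan passed in 2 and Adamts4 in 3 of the 8 fits without a library.

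The main peptide genes of AgRP neurons, Agrp and Npy, were higher in PLX3397 hypothalami without passing the test over all genes. Agrp, the feeding peptide that blocks melanocortin receptors (chromosome 8, 105566698 to 105637393 as annotated), was 11.8 ± 1.73 CPM in vehicle and 26.1 ± 10.5 CPM in PLX3397 libraries (SD, n = 4 each; 1.08 ± 0.23, edgeR adjusted p = 0.0699). Npy, the peptide these neurons also release (chromosome 6, 49822710 to 49829507), was 76.5 ± 11.2 and 150 ± 48.7 CPM (0.96 ± 0.22, adjusted p = 0.0891). Both were higher in all 4 PLX3397 libraries than in any vehicle library, and both were highest in PLX3397 M2, at 40.6 and 219 CPM. The leptin receptor gene Lepr had 0.42 (adjusted p = 0.0873) and Acvr1c 0.41 (adjusted p = 0.0992). Of 8 AgRP neuron genes 0 passed over all genes and 6 rose when adjusted over the list alone. The median was 0.41 (camera adjusted p = 0.000204; adjusted p = 0.398 with an estimated correlation; fry adjusted p = 0.0629). The members with a negative sign, given for that reason, were Npy2r (−0.13) and Otp (−0.06). Over the alternatives the adjusted p of Agrp ran from 8.61e-05, with DESeq2, to 0.213, and that of Npy from 0.000148, also with DESeq2, to 0.246. The annotated span of Agrp overlaps 7 other tested genes, Ctcf and Ripor1 among them, so its counts can hold their reads, while that of Npy overlaps none.

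The opposing melanocortin neurons showed no call. Pomc, the precursor of the appetite-lowering melanocortins, was 261 ± 471 CPM in vehicle and 23.8 ± 4.77 CPM in PLX3397 libraries (SD, n = 4 each; −2.28 ± 1.30, edgeR adjusted p = 0.449). The vehicle mean rests on vehicle F1, at 967 CPM against 22.4 to 28.5 CPM in the other 3. That library also held the pituitary hormone transcripts Gh at 2652 CPM, Prl at 173 CPM and Cga at 183 CPM, where Gh was at most 0.866 CPM elsewhere. Of 9 POMC neuron genes 0 passed with edgeR, over all genes or adjusted over the list alone, with camera adjusted p = 0.232. Nkx2-1 had 0.25, Pcsk1 0.14, Cartpt 0.12 and Prdm12 −0.45, with edgeR adjusted p from 0.233 to 0.432.

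The genes that rose included genes of the meninges and of basement membrane. Lama1, a laminin chain of basement membranes (chromosome 17, 67697259 to 67822647), rose 1.76-fold, from 17.8 ± 1.02 to 31.7 ± 5.91 CPM (SD, n = 4 each; 0.82 ± 0.10, edgeR adjusted p = 0.00935). Fam107a, an actin-associated gene of astrocytes and neurons, rose 1.56-fold, from 250 ± 18.3 to 389 ± 26.5 CPM (0.64 ± 0.07, adjusted p = 0.00563). Both were higher in all 4 PLX3397 libraries than in any vehicle library and passed in all 8 fits without a library. The others of the 10 highest named genes were Medag (1.14), Tbx18 (1.13), the endothelin gene Edn3 (1.04), Uaca (0.94), the collagen gene Col15a1 (0.81), the amino acid transporter gene Slc6a20a (0.79), Spp1 (0.69) and Itih5 (0.64), with adjusted p between 0.0124 and 0.0498. Slc6a20a passed in 7 and Uaca in 5 of the 8 fits without a library, Medag and Itih5 in 3, Tbx18 and Col15a1 in 2, and Edn3 and Spp1 in 1.

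Of 12 meningeal fibroblast genes 2 rose and 0 fell (7 and 0 adjusted over the list alone): the transporter gene Slc6a13 (0.73, edgeR adjusted p = 0.0218) and the retinoic acid synthesis gene Aldh1a2 (0.35, adjusted p = 0.0488). Dcn had 0.87 and Igf2 0.57 (adjusted p = 0.0852 and 0.13), and the list median was 0.37 (camera adjusted p = 5.37e-05; adjusted p = 0.33 with an estimated correlation). Of 27 collagen and basement membrane genes Lama1 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00469; adjusted p = 0.486 with an estimated correlation), with Col18a1 at 0.47, Lamb1 at 0.46 and Lama2 at 0.26 (edgeR adjusted p = 0.0968, 0.06 and 0.137). The list lost its call without PLX3397 F1 or vehicle F2 and with fry (adjusted p = 0.217). Of 19 reactive astrocyte genes 3 rose and 0 fell, also when adjusted over the list alone, and the list missed the camera threshold (adjusted p = 0.0529). They were the protease inhibitors Serpina3n (0.57, edgeR adjusted p = 0.0124) and Serping1 (0.40, adjusted p = 0.022) and the copper carrier ceruloplasmin, Cp (0.30, adjusted p = 0.0434), while Osmr had 0.55 (adjusted p = 0.181). Serpina3n passed in all 8 fits without a library, Slc6a13 in 3, Serping1 in 1 and Aldh1a2 and Cp in 0. Of 17 pan-neuronal genes the neurofilament gene Nefl, chosen after its value was seen, rose (0.17, adjusted p = 0.0421), and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000966; adjusted p = 0.33 with an estimated correlation).

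**Figure D3:**
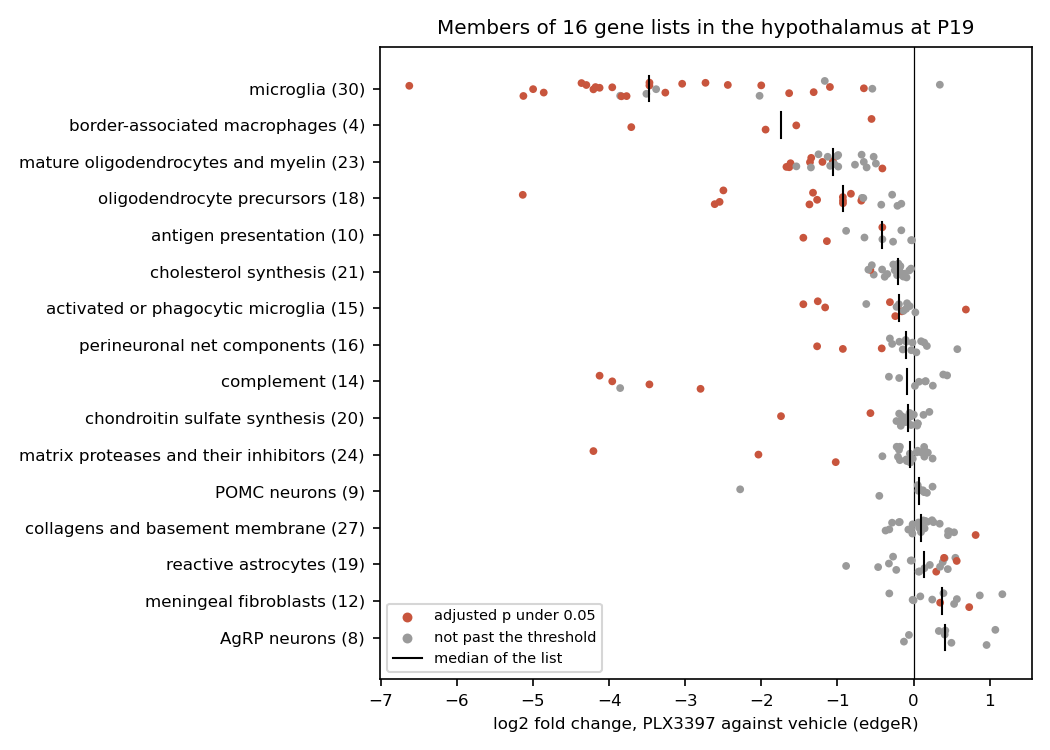
Log2 fold changes (edgeR, PLX3397 against vehicle, 4 libraries each) of the tested members of 16 gene lists, with points for genes and a vertical line for each list's median. Microglial genes have a median of −3.47, myelin genes −1.06 and precursor genes −0.93, whereas AgRP neuron genes have a median of 0.41 and meningeal fibroblast genes 0.37.

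All 21 cholesterol synthesis genes had a negative sign, with a median of −0.20 (camera adjusted p = 1.31e-05; adjusted p = 0.423 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell by 0.57 on the log2 scale (edgeR adjusted p = 0.0383) and was the only call of that list over all genes (in 1 of the 8 fits without a library), against 5 that fell adjusted over the list alone. Mvd, Fdps and Ebp had −0.59, −0.52 and −0.41 (adjusted p = 0.11, 0.134 and 0.136). Mitochondrially encoded genes (13 of 13 positive, median 0.12, camera adjusted p = 0.000239; adjusted p = 0.398 with an estimated correlation) and glucocorticoid-responsive genes (12 of 14 positive, median 0.30, camera adjusted p = 0.00297; adjusted p = 0.398 with an estimated correlation) had 0 calls with edgeR over all genes and 3 and 2 that rose adjusted over the list alone. Cell cycle genes had 0 calls either way and a median of −0.20 (camera adjusted p = 0.0418; adjusted p = 0.367 with an estimated correlation), a call lost without PLX3397 F2 or M1 or vehicle F1 or M1. With fry the cholesterol, mitochondrial and glucocorticoid lists did not pass (adjusted p = 0.11, 0.107 and 0.185), and the last lost its camera call without PLX3397 M2. The other 24 lists missed the camera threshold. Among the other receptor kinases the compound can bind, the Kit gene had 0.18 and Flt3 0.14 (edgeR adjusted p = 0.39 and 0.6; chosen after their values were seen).

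In all, 362 of 16894 genes passed in the comparison of treatments (edgeR, adjusted p under 0.05), 52 higher and 310 lower, of which 6 and 124 changed more than 2-fold. The median of all tested genes was −0.00, and in 353 of the 362 the 4 values of a group lay apart from the 4 of the other (11.2% of all tested genes did, where chance gives 2.86%). The count was 148, 146 and 224 without PLX3397 F2, M1 or M2 and 157, 138 and 162 without vehicle F2, M1 or M2, and 123 without vehicle F1 and PLX3397 M2 together, while DESeq2 called 1099. The spans of P2ry12, P2ry13, Ctss, Stab1, Adamts4, Fyn, Hapln1, Slc6a20a and Cp overlap another tested gene, and as the counting is not stated to use strand, their counts can include its reads.

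The microglial gene P2ry12 fell in each sex taken alone. It fell by 4.54 on the log2 scale in females (edgeR adjusted p = 0.00483) and by 5.21 in males (adjusted p = 0.0023), lower in both PLX3397 libraries of each sex than in its vehicle libraries. In males Rnf122, a ubiquitin ligase gene (−2.06, adjusted p = 0.00185), fell too, and the adenylate kinase gene Ak4 (2.65, adjusted p = 0.00543), the glycine receptor subunit Glrb (0.79, adjusted p = 0.00574) and the pseudogene Oaz1-ps (2.95, adjusted p = 0.00666) rose. In females the actin phosphatase gene Ssh2 (1.58, adjusted p = 0.00421), the keratin gene Krt14 (1.86, adjusted p = 0.00984) and Hsd17b12 (0.76, adjusted p = 0.0124) rose, and Cdc42se1 (−1.37, adjusted p = 0.00421) and Usp50 (−4.94, adjusted p = 0.00483) fell. Krt14 was 25.5 and 32.0 CPM in PLX3397 F1 and F2 and 6.42 to 8.11 CPM in the other 6 libraries.

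With 2 libraries per arm, 61 genes passed in females (14 higher, 47 lower) and 260 in males (32 higher, 228 lower). Of these, 36 were lower in both sexes, where independent lists would share 0.634, and 3 were higher in both, where they would share 0.0265. Of the 280 genes past in either sex 240 had the same sign in both, against 10220 of all 16894 tested genes. The vehicle males stood apart in haemoglobin, with Hbb-bs at 66.9 and 71.9 CPM against 9.41 to 30.9 CPM in the other 6 libraries. The female count was 36, 31 and 38 without PLX3397 F1, PLX3397 F2 or vehicle F1, of which the last had 20 higher and 18 lower and shared 15 of the 61, and the male count 122, 169, 171, 148 and 87 without PLX3397 M2, vehicle F1, F2, M1 or M2, with 49 higher and 99 lower without vehicle M1 and 33 higher and 54 lower without vehicle M2. With vehicle F1 and PLX3397 M2 left out together the counts were 37 (18 higher, 19 lower) and 48 (7 higher, 41 lower), and DESeq2 called 424 and 834.

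A small set of single genes passed the test for a difference between the sexes in the effect of PLX3397. None of them was in the microglial, myelin or AgRP lists. With 2 libraries per sex and treatment, jumps by pair and a response by sex cannot be told apart. Ssh2 was 18.3 CPM on average in vehicle females and 54.9 CPM in PLX3397 females, against 58.3 and 50.2 CPM in males (effect in females minus effect in males 1.80 ± 0.11 on the log2 scale, edgeR adjusted p = 0.0303). Usp50, a ubiquitin peptidase family gene, was 5.24 and 0.169 CPM in females and 5.68 and 5.91 CPM in males (−5.00 ± 0.36, adjusted p = 0.0336). The log2 effect in females was also above that in males for Fam205a4 (2.53, adjusted p = 0.0336) and Hsd17b12 (0.93, adjusted p = 0.0413). It was below that in males for Tmub2 (−1.29) and Cdc42se1 (−1.07; adjusted p = 0.0336 each). Fam205a4 fell in males, from 8.74 to 1.55 CPM on average, and was 8.78 and 9.03 CPM in vehicle and PLX3397 females. For Hsd17b12, as for Ssh2, the vehicle females stood apart, at 42.8 CPM on average against 69.3 to 77.9 CPM in the other sets. Without a library in turn, Ssh2 passed in 6 of 8 fits, Usp50 in 4, Tmub2 in 2, Fam205a4 in 1 and Hsd17b12 and Cdc42se1 in 0. As lists, 18 of 38 passed camera for the difference, and 0 with an estimated correlation. Myelin genes had a median of −0.58 in females and −1.57 in males (camera adjusted p = 2.03e-11; adjusted p = 0.417 with an estimated correlation), precursor genes −0.60 and −1.27 (adjusted p = 4.47e-10; adjusted p = 0.338 with an estimated correlation). Microglial genes had −3.00 and −3.97 (camera adjusted p = 1.75e-05, or 0.417 with an estimated correlation). AgRP neuron genes had 0.30 and 0.50 (camera adjusted p = 0.00633, or 0.417 with an estimated correlation). The mean log2 level of the microglial list was 1.65, 1.49, 1.47 and 0.946 in PLX3397 F1, F2, M1 and M2, against 3.56 to 3.63 in vehicle. PLX3397 M1 was thus near the females, and the lower male level leaned on PLX3397 M2. For the myelin list PLX3397 M1 (6.02) lay between F1 and F2 (6.39 and 5.82). Vehicle males (7.11 and 7.27) lay above vehicle females (6.73 and 6.75) in that list.

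In all, 13 of 16894 genes passed for this difference (6 higher, 7 lower in females), and 1015 had an unadjusted p under 0.05. The differences for Agrp (−0.92, edgeR adjusted p = 0.818), Npy (−0.79, adjusted p = 0.828) and Csf1r (1.06, adjusted p = 0.866) did not pass. Agrp, with 1.54 in males (adjusted p = 0.0366) and 0.61 in females (adjusted p = 0.462), is therefore not shown to differ between them. Each fit without a library leaves a lone library in a set of sex and treatment. Without PLX3397 F1 or without PLX3397 F2 none of the 13 kept a call. The other such fits kept only part of the 13, and DESeq2 called 143. Ssh2, Usp50 and Cdc42se1 overlap other tested genes, and after counts of overlapping genes were summed, a fit added after the data had been seen, edgeR called 0 of 13877 loci (812 at an unadjusted p under 0.05). Tmub2 (−1.29), Fam205a4 (2.53) and Hsd17b12 (0.93) overlap no tested gene, so summing added nothing to their counts. Their differences stayed by construction, with edgeR adjusted p = 0.0611 each in that fit.

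**Figure D4:**
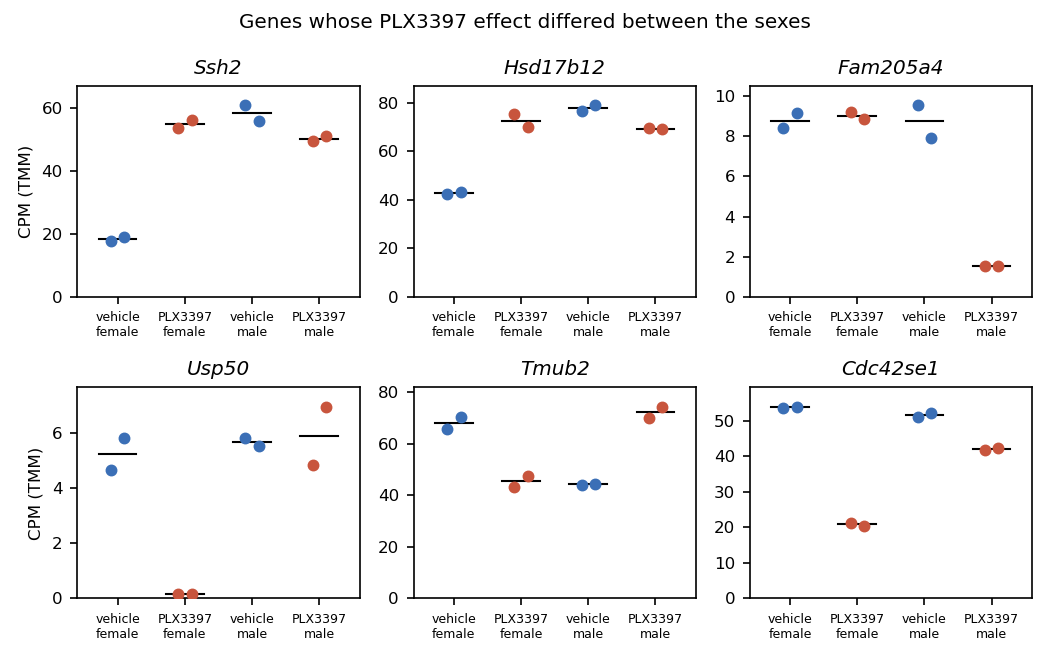
Levels in CPM of 6 genes that passed the test for a difference between the sexes in the PLX3397 effect (Ssh2, Hsd17b12, Fam205a4, Usp50, Tmub2, Cdc42se1). Each of the 8 libraries is drawn by sex and treatment, with points for libraries and horizontal lines for means of 2. Usp50 lies near 0 in PLX3397 females, at a mean of 0.169 CPM, against means of 5.24 to 5.91 CPM in the other 3 sets of libraries.

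Females and males differed mainly in genes of the sex chromosomes. Xist, the RNA that silences an X chromosome (chromosome X, 103460366 to 103483254), was 431 ± 40.4 CPM in females and 0.455 ± 0.245 CPM in males (SD, n = 4 each; edgeR adjusted p = 3.48e-05). The Y-linked genes Ddx3y, Kdm5d and Eif2s3y were 82.3 ± 5.34, 44.0 ± 2.25 and 42.2 ± 5.71 CPM in males and at most 0.0215 CPM on average in females (adjusted p = 3.76e-05, 0.000103 and 0.000709). Ddx3x, which escapes X inactivation, was higher in females (0.42, edgeR adjusted p = 0.017), in 3 of the 8 fits without a library. The 2 autosomal genes past the test were Cnih3, an AMPA receptor auxiliary subunit gene, higher in females (31.3 ± 3.04 against 12.9 ± 1.58 CPM; 1.28, adjusted p = 0.00176), and Lrrc61, lower in females (5.91 ± 0.827 against 28.0 ± 2.29 CPM; −2.25, adjusted p = 3.76e-05) and overlapping the tested gene Rarres2. In all, 10 genes passed, 4 higher and 6 lower in females, and DESeq2 called 52.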

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

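The count of all pairings of libraries, the fit on summed counts and the tests on genes that overlap no other gene or have no near-identical copy were chosen only after the results were seen. In single libraries, 14 of 196 checked groups of 4 held a library far from the other 3, where chance gives 9.8. In vehicle F1, Pomc was 967 CPM (22.4 to 28.5 CPM in the other vehicle libraries), P2ry12 15.2 CPM (21.2 to 22.1 CPM), Ctss 42.6 CPM (36.1 to 37.2 CPM) and the mean log2 level of the pituitary list 5.99 (1.13 to 1.49). In vehicle F2, Spp1 was 11.5 CPM (14.1 to 14.5 CPM), Ak4 15.3 CPM (9.15 to 10.1 CPM) and the mean log2 level of the AgRP neuron list 4.26 (4.12 to 4.13). In PLX3397 F1, Hsd17b12 was 75.5 CPM (69.0 to 69.8 CPM in the other PLX3397 libraries), Selplg 2.41 CPM (0.976 to 1.17 CPM), Plat 66.3 CPM (56.6 to 58.0 CPM) and Crybb1 0.241 CPM, where the other 3 had a count of 0. In PLX3397 F2, Col15a1 was 26.1 CPM (36.1 to 37.8 CPM) and Lyz2 4.48 CPM (2.92 to 3.04 CPM), and in PLX3397 M2, Glrb was 168 CPM (183 CPM in each of the other 3).

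Genes of unrelated functions passed edgeR's test for a difference between the sexes in the response to PLX3397. The effect in females minus the effect in males was 1.80 for the actin phosphatase gene Ssh2, 2.53 for Fam205a4, 1.45 for the ciliary transcription factor Rfx3 and 0.93 for Hsd17b12, and −5.00 for Usp50, −4.22 for Fam220a, −3.53 for Oaz1-ps, −3.03 for Ak4, −1.29 for Tmub2, −1.07 for Cdc42se1 and −0.90 for the calcineurin subunit gene Ppp3cb. Rfx3 was 29.8 CPM in vehicle and 21.7 CPM in PLX3397 females and 33.0 and 8.82 CPM in males. Fam220a was 14.2 and 1.11 CPM in females and 10.5 and 15.3 CPM in males, and Ppp3cb was 169 and 99.3 CPM in females and 164 and 181 CPM in males. Against a floor of 3 counts per library, Gm4613 was at least 22.3-fold higher after PLX3397 in females and at least 42.7-fold lower in males, a log2 difference of at least 9.90, and Gm11007 was at least 143-fold higher in females, a log2 difference of at least 7.49.

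These differences may come from single genes that jump in any pair of libraries, from reads of overlapping genes or from near-identical copies, against a response that differs by sex. Among 15572 genes with a mean of at least 1 CPM, the 4 pairs of libraries that share sex and treatment stood at least 2-fold apart from all other libraries in 6.75 genes on average, which is not above the highest of the other 24 pairs, 7 (mean 3.42), yet only 1 of 105 pairings of the libraries had a mean as large (exact p = 0.00952), so jumps by pair and a response by sex cannot be told apart with 2 libraries per pair. Of the 13 genes 53.8% overlap another tested gene, against 30.5% of all tested genes (Fisher's exact test, one-sided, p = 0.0673), and after counts were summed 0 kept a call, in Usp50 (from −5.00 to −0.07), Ssh2 (1.80 to 0.90), Cdc42se1 (−1.07 to −0.13), Fam220a (−4.22 to −0.11) and Ppp3cb (−0.90 to −0.35) with a much smaller difference, which summing with an abundant partner also brings, in Gm4613 with a smaller fitted one (adjusted p = 0.0732) and in Oaz1-ps with most of it kept (−3.53 to −2.62, adjusted p = 0.103), so this stays open for the overlapping genes. By their annotated coordinates 6 genes overlap no tested gene, so no overlapping tested gene is there to split reads with. This follows from the coordinates, was not tested on reads and does not cover copies at other loci. Summing added nothing to the counts of these 6, so their differences stayed by construction. Their adjusted p moved to between 0.0611 and 0.0750, because fewer small p-values remained among the loci. Near-identical stretches in annotated transcripts of other genes were found for 53.8% of the 13 against 43.6% of 500 random genes (Fisher's exact test, one-sided, p = 0.323). Genes at the same locus were not left out of that search, so it is not separate from the overlap of genes. It leaves shared reads open for the 7 genes with such a stretch. The 6 others (Ssh2, Tmub2, Cdc42se1, Ppp3cb, Hsd17b12 and Rfx3) had none, and 3 (Tmub2, Hsd17b12 and Rfx3) had neither stretch nor overlap.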

How the results depend on the processing

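The fits without vehicle F1 and PLX3397 M2, the bias-adjusted deviances and the summed overlapping genes were chosen only after the results were seen. With the replicate label as a block, edgeR called 79 genes in the comparison of treatments, 0 in females (1433 at an unadjusted p under 0.05), 3 in males and 0 for the difference between the sexes (847 unadjusted). The labels are not said to pair animals, the deviations of libraries that share a label correlated at 0.0296 to 0.101, and vehicle M2 correlated best with PLX3397 M1, not with its own label. DESeq2 called 1099 genes in the comparison of treatments, 361 of the 362 among them, 68.8% of them lower against 85.6% with edgeR, and 424 in females, 834 in males, 143 for the difference and 52 for females against males. The cause was not tested, though on simulated counts DESeq2 both recovered more changed genes and made more false calls. Without vehicle F1 and PLX3397 M2 together the counts were 123, 37 in females (8 shared) and 48 in males (25 shared). Without a covariate in a fit on each sex alone, which has fewer libraries, 32 genes passed in females and 75 in males. In females limma-trend with a pseudocount of 1 called 96 and bias-adjusted edgeR 98, and the cause was not tested. With overlapping genes summed, 0 of 13877 loci passed for the difference (812 unadjusted). Leaving out each library in turn, a lone remaining library being assumed to vary like the other groups, gave 138 (without vehicle M1) to 361 genes in the comparison of treatments, 31 (without PLX3397 F2) to 83 in females, 87 (without vehicle M2) to 243 in males, 0 (without PLX3397 F2; 1103 unadjusted) to 19 for the difference, 8 to 14 for females against males and 13 to 17 lists. With an estimated correlation camera called 0 of 38 lists (5 unadjusted), where fry called 14 (2 higher, 12 lower), 9 of them shared. The fold change of Acan, −0.03, was 0.040 with quantile normalization, 0.0099 without PLX3397 M1, 0.020 without vehicle M2 and −0.058 at its lowest. Quantile normalization turned the direction of the mitochondrial list (camera adjusted p = 0.616). The other alternatives gave 297 to 427 genes in the comparison of treatments. Among single genes and lists, 2391 results kept direction and side of the threshold, 407 lost and 44 gained a call and 4 turned direction. Depth limits single genes near 0.0451 to 0.0557 CPM.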

Other observations

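The tests on oligodendrocyte and AgRP neuron genes, and the choice of most genes named in this part, were made only after the results were seen. Some guidance molecules of the semaphorin family fell. Of 22 tested genes annotated to semaphorin receptor binding 5 fell, where 0.493 would by chance (Fisher's exact test, one-sided, adjusted p = 0.0274 over 3389 terms). The related terms semaphorin-plexin signaling pathway (adjusted p = 0.119) and chemorepellent activity (0.212) missed the threshold, and of the 27 genes of the axon guidance list 1 fell, Sema3d, with a median of 0.00 (camera adjusted p = 0.998). The 5 genes were Sema4d (−0.85, edgeR adjusted p = 0.0116), Sema5a (−0.39, adjusted p = 0.0276), Sema5b (−0.56, adjusted p = 0.036), Sema6a (−0.54, adjusted p = 0.0467) and Sema3d (−0.96, adjusted p = 0.00563). Plxnb3, a receptor of this family, fell from an average of 80.7 to 18.8 CPM (−2.09 ± 0.22, edgeR adjusted p = 0.00563). Nfasc, the neurofascin gene, fell as well (−1.10 ± 0.08, adjusted p = 0.00306), as did the calcium-sensing receptor gene Casr (−1.35, adjusted p = 0.00404). The myelination term held 13 genes that fell of 47, where 1.05 would by chance (adjusted p = 6.66e-08), and 20 terms passed among the genes that fell and 4 among those that rose. In the same libraries the precursor and myelin lists had medians of −0.93 and −1.06. The semaphorin genes are therefore not shown to be a theme of their own.

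Protease inhibitor genes were among those that rose. Of 41 genes annotated to serine-type endopeptidase inhibitor activity 5 rose, where 0.149 would by chance (Fisher's exact test, one-sided, adjusted p = 0.000712), among them Serpina3n, Serping1, the neuroserpin gene Serpini1 (0.39, edgeR adjusted p = 0.00518), Itih5 and Itih2 (0.63, adjusted p = 0.0351). Serpina3n and Serping1 are also 2 of the 3 calls of the reactive astrocyte list, and the meningeal fibroblast list, with 7 of 12 genes higher adjusted over the list alone, had a median of 0.37 in the same libraries, so the inhibitors are not shown to be a theme of their own. Postn, which encodes the matrix protein periostin, rose from 4.69 CPM on average (1.37 ± 0.13, edgeR adjusted p = 0.0046), and the apolipoprotein D gene Apod (0.43, adjusted p = 0.0046) and the alarmin gene Il33 (0.43, adjusted p = 0.0447) rose too. Each of Plxnb3, Nfasc, Postn and Apod was separate in all 4 PLX3397 libraries from all 4 vehicle libraries.

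The lower oligodendrocyte genes may come from scaling, from less white matter in the PLX3397 dissections or from the compound acting on the lineage itself, against an effect that follows the loss of microglia, which the design cannot separate from the compound. A wrong library factor moves all genes alike, so it cannot part these lists from the other genes. The median of the 41 precursor and myelin genes was below that of all tested genes. The difference was −1.0 (95% bootstrap interval over genes −1.25 to −0.82), which argues against scaling as the cause. That interval holds no spread between animals, and the bound was set once the result was known. Less white matter would lower myelin genes most; the myelin list had a median of −1.06 and the precursor list −0.93, and 4 precursor genes lay below the lowest myelin gene, which does not decide it. Pdgfra, a kinase the compound can bind and a marker of early precursors, had −0.21 (edgeR adjusted p = 0.182), a single marker that decides nothing, so an action of the compound on the lineage stays open.

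The higher Agrp and Npy, on average 1.02 on the log2 scale, may come from a dissection that held more arcuate nucleus, from a larger share of neurons or from PLX3397 M2 alone, against a response of AgRP neurons. Over 10 other arcuate markers the median was 0.089 (95% bootstrap interval over genes −0.15 to 0.51, without vehicle F1). Single markers ran from −0.46 for Prdm12 to 1.74 for Slc6a3. The median argues against a larger arcuate share as the whole cause, though not as a part of it. It cannot exclude such a share, as the interval holds no spread between animals. An earlier, stricter bound left this undecided and was changed once the result was known. Pan-neuronal genes had a median of 0.15 (interval over genes 0.03 to 0.20), which argues against a larger share of neurons as the whole cause. Without PLX3397 M2 the mean was still 0.79, which excludes that library as the only source.

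In the comparison of treatments 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many as 362 genes. The highest other, the split by sex, gave 10. This share is the smallest that 35 splits can give, so it makes chance unlikely rather than excluded. The other splits mix treated and vehicle libraries, which can widen their spread and lower their counts. Differences of litter or dissection between the groups were not tested. For females against males 2 of 35 splits gave 10 or more, the other being the split by treatment with 427. As that split is always among the 35, this share could not pass and decides nothing. The highest of the rest gave 4, and Xist and Ddx3y matched the sex label in all 8 libraries. For gene lists 7 of 35 splits gave 14 or more past the camera threshold, the highest 15, so chance is not excluded for the number of lists.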
